A study of Mus musculus with 8 samples.

How the data were processed

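The series holds RNA-seq of mouse utricles, the gravity-sensing organs of the inner ear, from embryonic day 15.5. There were 4 libraries from embryos heterozygous for a deletion of exon 4 of Rest and 4 from wild-type embryos. Per the labels' protocols, each library pooled RNA from 7 to 9 mice. From 200 to 300 ng of total RNA, cDNA was made from an oligo-dT primer with template switching. It was amplified in 12 PCR cycles, and 125 pg of it was tagmented with a transposase kit and sequenced as paired reads of 126 bases. Groups were taken from the genotype label. The titles call the mutant libraries knockouts, while the genotype label gives a heterozygous deletion of 1 exon. The age label of wild-type replicate 4 reads 15.6 in place of 15.5, and its strain label also differs from the others by 1 digit. Both were taken as given and used nowhere.

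The authors deposited a file of gene counts for each library. Per the submitters' processing notes, reads were aligned to GRCm38.p4 with STAR 2.5.2a, and DESeq2 was used, with no version given. The deposited counts are whole numbers of read pairs per gene, not normalized. The strand-specific columns summed to within 0.996 to 1.00 of each other and each to 53.2% to 53.4% of the unstranded column. The unstranded column was therefore used, and reads of overlapping or antisense genes cannot be told apart by strand. Lines that name no gene (unmapped, multimapping, outside genes, ambiguous) held 25.2% to 33.9% of read pairs and stayed out of library sizes and tests. Multimapping reads were not counted for any gene, so genes with near-identical copies, such as Rps3a1 and the pseudogene Rps3a2, have uncertain levels.

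The authors also deposited a table of normalized counts, a signal obtained by dividing gene counts by a size factor per library. It holds 21369 genes and 7 libraries, without wild-type replicate 4. Its size factors could be recovered from the values: 100% of the values became whole reads (tolerance 0.001 reads) and equalled the deposited counts. The count test was therefore also run on these libraries and genes, an alternative chosen after seeing the data, and it called 129 genes.

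Read pairs on genes ranged from 20.4 to 24.6 M per library. Of 48823 gene identifiers, 48349 were found in GENCODE release M21 (GRCm38), which gave symbols, biotypes and coordinates. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16990. Counts were scaled by TMM factors (trimmed mean of M values), and genotypes were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test. Benjamini-Hochberg adjustment was made over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values were computed with edgeR from TMM-scaled library sizes and are given as mean ± SD over 4 libraries. For single genes, library measures and the median of the genes near Rest, an exact two-sided permutation test over 70 assignments was used (35 for Rest in the authors' 7 libraries), which cannot give a p below 0.0286.

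There were 26 gene lists fixed before the data were examined, for REST targets, hair cell groups, other cell types of the inner ear and stress responses. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation and with fry. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The genes named in the text followed a rule fixed at the same time: Rest, Srrm4, Srrm3, Atoh1, Pou4f3, Gfi1 and Myo7a in any case; the 12 protein-coding genes with the largest change in each direction among those past the threshold, with non-overlapping groups and a mean of at least 2 CPM; and up to 4 members of each list past the threshold with the smallest adjusted p, or the 2 most highly expressed where none passed. A further part of the rule, on genes near genomic RE1 sites, was not applied because no genome sequence was used here. Genes named outside the rule are Afp, Alb, Asb1, Rbp4, Trf, Ttr, Gm5869, Cfap161, Chrnb2, Drc1, Rundc3a, Tekt2 and Tekt4, and 1 gene that the rule chose is not reported here.

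The test was checked on simulated counts for this comparison of 4 against 4 libraries, with 200 changed genes among about as many genes as were tested. At a fold of 1.5, 25.5% of changed genes were recovered with 3 false calls, at 2-fold 69.5% with 12, and at 4-fold 95% with 7. Changed genes were drawn only from those with a mean above 20 counts, so recovery of genes with fewer counts was not checked. With no changed gene there was 1 call. In a simulated list test, 0 of 20 unchanged lists gave p under 0.05. The simulated genes varied independently of each other. This does not check the preset correlation for lists whose genes vary together, such as the REST target list (estimated correlation 0.22). Alternatives were DESeq2 1.42.0, other size factors, no or a stricter filter (1 CPM in 4 libraries), limma-voom with and without quality weights, the replicate number as a block, a covariate for the mix of male and female embryos, haemoglobin and mitochondrial genes left out, thresholds of 0.01 and 0.1, and each library left out in turn. Chosen after seeing the data were the authors' libraries and genes, leaving out wild-type replicates 3 and 4 together, and leaving out chromosomes 1, 3 and 9. Libraries of a group were compared with a chi-square statistic, and no pair agreed within sampling noise. The labels say that libraries were pools of mice but not whether pools shared litters, so p-values measure the spread between these pools.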

Results

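Gene expression was measured in the utricles of mouse embryos, in 4 libraries from Rest heterozygotes that lack exon 4 on 1 allele and 4 libraries from wild-type embryos. REST is a repressor that silences neuronal genes in other cells. Exon 4 of its gene is an alternative exon whose inclusion gives a truncated protein, and the comparison asks what its loss does to expression in an organ whose hair cells use many neuronal genes. Read pairs on genes were 23.5 ± 0.887 M (SD, n = 4) in the mutant and 22.3 ± 1.63 M (SD, n = 4) in the wild-type libraries. Read pairs outside annotated genes made up 15.3% ± 3.07 and 19.9% ± 1.65, respectively (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest possible). Genes with at least 1 read numbered 23749.8 ± 258 in mutant and 24469.5 ± 177 in wild-type libraries (exact permutation p = 0.0286). Neither measure overlapped between genotypes, with 23408 to 23989 genes in mutant and 24265 to 24687 in wild-type libraries. A difference between the libraries themselves therefore cannot be told apart from the genotype. No fit adjusted for these measures, and whether they bear on the lower genes was not tested.

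Rest itself (chromosome 5, 77265491 to 77286432, GRCm38) was at 127 ± 3.20 CPM in mutant and 116 ± 7.35 CPM in wild-type libraries (SD, n = 4 each), a ratio of 1.09. The exact permutation p was 0.0286, the smallest the design allows, but it was 0.229 on CPM without TMM factors (ratio 1.06), and edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.456. In the authors' normalized counts of 7 libraries the ratio was 1.07 (exact permutation p = 0.0286, also the smallest possible). Gene-level counts do not show which exons were used, so they check neither the deletion nor the label. None of the 24 members of the list of REST, its splicing regulators and corepressors passed the threshold over all genes tested, and 1 passed adjusted over the list alone (median log2 change -0.02, camera adjusted p = 0.918). Srrm4, a splicing factor that promotes inclusion of neuronal exons, was at 11.2 ± 1.23 against 14.1 ± 2.23 CPM, and its relative Srrm3 at 0.318 ± 0.153 against 1.19 ± 0.250 CPM (edgeR adjusted p = 0.356 and 0.0515).

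Several genes of secretory granules, synapses and the axon fell in the mutant utricles, some to nearly undetectable levels. Scg3, which sorts hormones into secretory granules, was at 0.901 ± 0.393 CPM in mutant and 19.6 ± 3.19 CPM in wild-type libraries, and the granule protein gene Chga at 2.44 ± 0.823 and 30.5 ± 6.03 CPM (SD, n = 4 each). Snap25, a core protein of vesicle fusion, fell from 18.8 ± 7.43 to 2.48 ± 0.850 CPM, the sodium channel subunit gene Scn3b from 20.4 ± 1.62 to 3.58 ± 0.239 CPM, and the neurofilament gene Nefm from 254 ± 27.1 to 100.4 ± 3.30 CPM. The log2 changes were -4.44 ± 0.29 for Scg3, -3.65 ± 0.23 for Chga, -2.93 ± 0.30 for Snap25, -2.51 ± 0.12 for Scn3b and -1.34 ± 0.08 for Nefm (SE). Their adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 2.41e-05, 1.88e-05, 0.000775, 2.76e-06 and 1.88e-05.

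These genes belong to the list of canonical REST targets, of which 16 of the 51 members tested fell, 0 rose and 35 did not pass, with 24 lower adjusted over the list alone. The median log2 change was -0.88, and 46 of 51 had a negative value (camera adjusted p = 4.41e-48, and adjusted p = 0.0249 with an estimated correlation). The neuronal gene content of wild-type replicate 3 was higher than that of the other wild-type libraries: its median deviation over this list was 0.82 against 0.28 to 0.30. Without that library the median was -0.57 (camera adjusted p = 1.04e-37, at the preset correlation only), still with a lower level of canonical REST target genes.

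**Figure D1:**
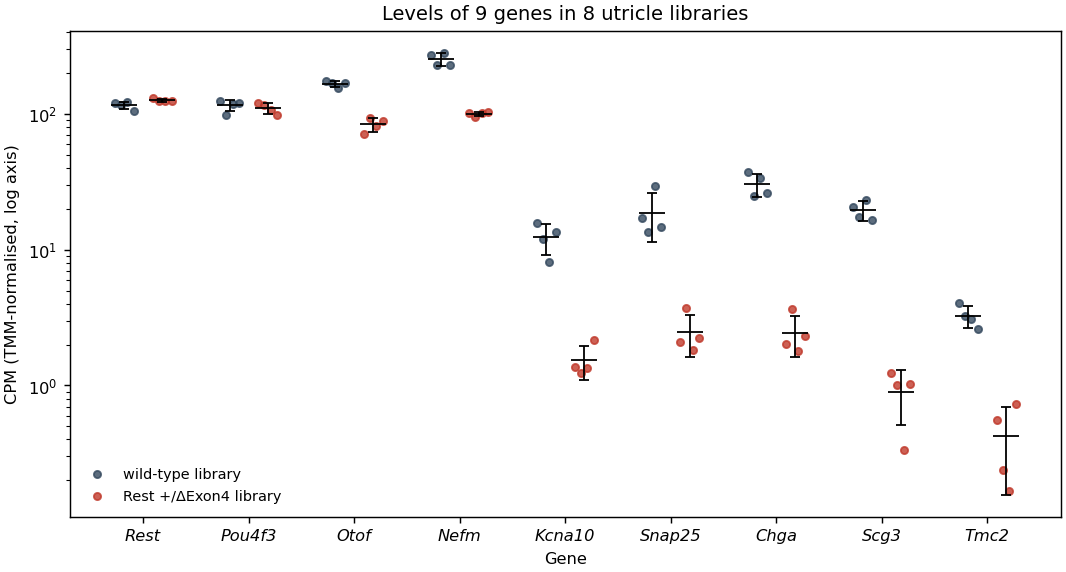
Levels of 9 genes (x axis) in each library as TMM-scaled CPM (y axis, log scale), with wild-type libraries in dark blue and mutant libraries in red; horizontal ticks are means and bars the SD over 4 libraries. Rest and Pou4f3 overlap or nearly overlap between genotypes, while every mutant library lies below every wild-type library for Otof, Nefm, Kcna10, Snap25, Chga, Scg3 and Tmc2.

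Over all 16990 genes tested, 173 were lower and 25 higher in the mutant libraries at an adjusted p under 0.05 (edgeR, Benjamini-Hochberg). Of the lower genes 91 changed by more than 2-fold and 16 by more than 8-fold, and 153 were protein coding. For all 173 lower and 24 of the 25 higher genes the libraries of both groups did not overlap. Selection at this threshold favours such genes, so this is no separate support for the calls. Of all genes tested 7.88% did not overlap, against 2.86% by chance. Every left-out library changed the counts. The number of lower genes was 107 and 106 without mutant replicates 3 and 4, and 105, 114, 106 and 112 without wild-type replicates 1 to 4. The number of higher genes was 15 without mutant replicate 1, 14 without wild-type replicate 1 and 12 without wild-type replicate 3.

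The largest falls among protein-coding genes included, besides Scg3 and Chga, the membrane protein gene Tmem179 (log2 change -5.08 ± 0.30, SE), the rabphilin gene Rph3a (-4.63 ± 0.50), Nrsn1 (-4.42 ± 0.32), the vesicular glutamate transporter gene Slc17a6 (-3.44 ± 0.58), Gm1113 (-3.36 ± 0.31), Gdap1 (-3.23 ± 0.37), its relative Gdap1l1 (-3.22 ± 0.26), the potassium channel gene Kcna10 and Lhfpl4 (-2.87 ± 0.29). Tmem179 was at 0.393 ± 0.247 CPM in mutant and 13.6 ± 1.19 CPM in wild-type libraries (SD, n = 4 each). Adjusted p by edgeR's test ranged from 1.87e-05 for Tmem179 to 0.0175 for Slc17a6. The call of Slc17a6 was lost without mutant replicate 4 (adjusted p = 0.0518) and without wild-type replicate 3 (adjusted p = 0.0575).

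Hair cell genes of synapses, ion channels and calcium handling fell as a group. Of 32 tested, 8 fell and none rose over all genes, and 14 were lower and 3 higher adjusted over the list alone (median log2 change -0.51, camera adjusted p = 6.88e-13, and adjusted p = 0.00707 with an estimated correlation). Otof, required for transmitter release by hair cells, was at 84.2 ± 9.82 CPM in mutant and 167 ± 8.80 CPM in wild-type libraries. Kcna10 was at 1.53 ± 0.429 and 12.4 ± 3.25 CPM and the calcium pump gene Atp2b2 at 17.1 ± 3.22 and 44.0 ± 4.22 CPM (SD, n = 4 each; edgeR adjusted p = 0.000319, 0.000189 and 0.000775). Of this list 7 members are also on the REST target list, and outside it 6 of 25 fell (median -0.32, camera adjusted p = 9.98e-08, at the preset correlation only).

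Genes of the hair bundle, the mechanosensitive organelle of the hair cell, also fell: 7 of 45 over all genes, none rose, and 16 were lower adjusted over the list alone (median log2 change -0.32, camera adjusted p = 2.68e-10, but adjusted p = 0.157 with an estimated correlation). No member is on the REST target list, but Lhfpl5 has a match to the RE1 consensus in an annotated transcript. Absence from that list therefore does not exclude that members are REST targets. Tmc2, a component of the mechanotransduction channel of young hair cells, was at 0.425 ± 0.268 CPM in mutant and 3.27 ± 0.608 CPM in wild-type libraries. Fscn2, an actin crosslinker, was at 6.69 ± 1.31 and 15.1 ± 1.48 CPM, Xirp2 at 19.4 ± 1.05 and 33.96 ± 2.92 CPM, and Lhfpl5 at 32.9 ± 5.24 and 52.9 ± 2.26 CPM (SD, n = 4 each; edgeR adjusted p = 0.00392, 0.00211 and 0.0135; 0.00477 for Tmc2). Myo7a, a hair bundle myosin, was at 31.5 ± 3.88 and 41.6 ± 5.96 CPM and did not pass (adjusted p = 0.199).

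The list of hair cell transcription factors and early hair cell genes did not move as a group (26 tested, median log2 change -0.04, camera adjusted p = 0.0794, and adjusted p = 0.673 with an estimated correlation). Pou4f3 was at 111 ± 9.78 CPM in mutant and 116 ± 11.5 CPM in wild-type libraries, and Gfi1 at 12.4 ± 3.13 and 16.6 ± 4.91 CPM. Atoh1, the factor that starts hair cell differentiation, was at 60.4 ± 16.1 and 38.3 ± 10.4 CPM (SD, n = 4 each). The edgeR adjusted p were 0.783, 0.477 and 0.238. Of this list 3 members fell: Acbd7 (-0.88 ± 0.10, SE), the Notch ligand gene Dner (-1.56 ± 0.18) and the nicotinic receptor gene Chrna10 (4.50 ± 0.968 against 9.04 ± 1.45 CPM). Adjusted over the list alone, 6 were lower and 3 higher. The list test passed without mutant replicate 1 (adjusted p = 0.0217) or wild-type replicate 2 (0.0146). The call of Chrna10 was lost in 6 of the 8 fits that leave out a library, with adjusted p from 0.0745 to 0.104 in these.

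Synaptic vesicle and exocytosis genes fell in 8 of 44 cases and none rose, with 13 lower adjusted over the list alone (median log2 change -0.32, camera adjusted p = 2.34e-15, but adjusted p = 0.157 with an estimated correlation). The vesicle calcium sensor gene Syt2 was at 0.796 ± 0.386 CPM in mutant and 4.43 ± 0.582 CPM in wild-type libraries (SD, n = 4 each, edgeR adjusted p = 0.00335). Of the members 15 are also REST targets, and outside that list 3 of 29 fell (median -0.10, camera adjusted p = 0.000652 at the preset correlation). These 29 genes were not tested with an estimated correlation, so a fall apart from REST targets is not established. Ganglion neuron genes fell in 2 of 22 cases, Nefm and Nefl (72.4 ± 11.6 against 134 ± 24.6 CPM), and 4 were lower adjusted over the list alone (median -0.30, camera adjusted p = 0.000316, but adjusted p = 0.549 with an estimated correlation). Without wild-type replicate 3 the median of the ganglion list was -0.01 (adjusted p = 0.131).

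**Figure D2:**
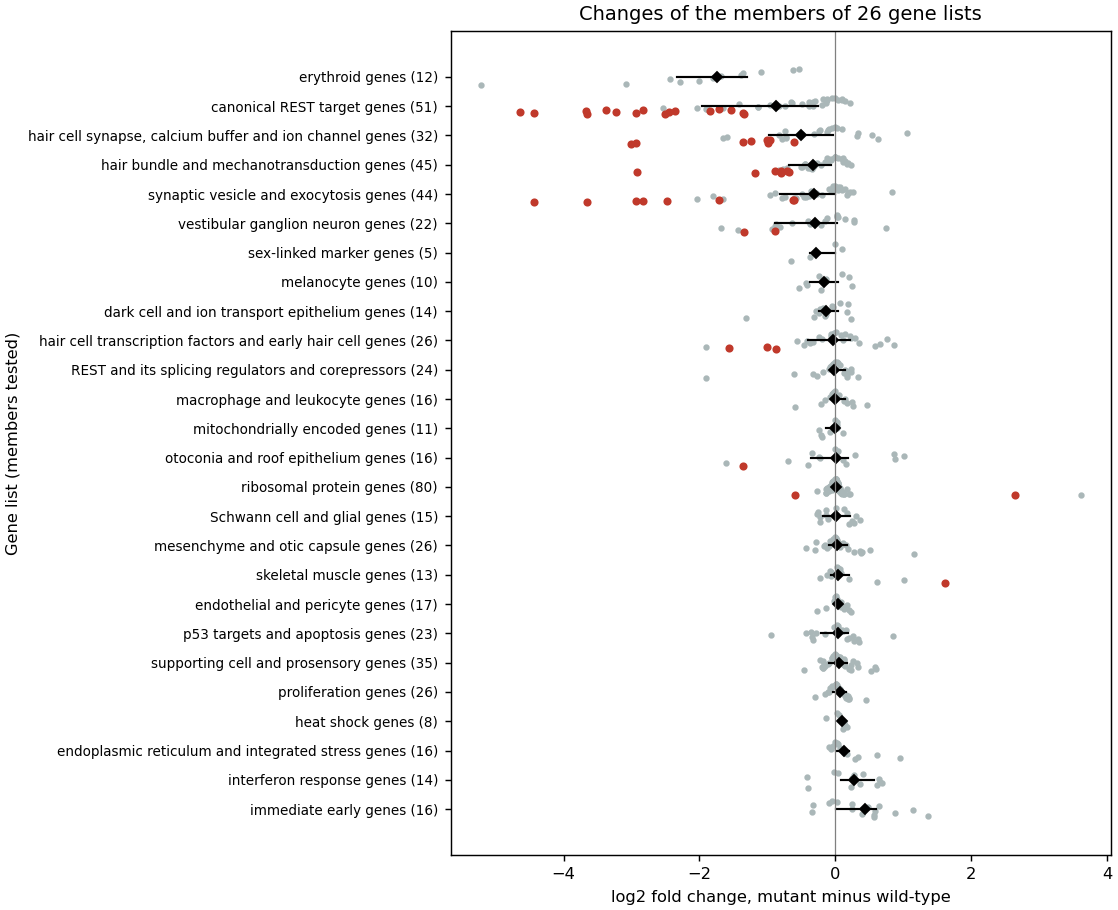
log2 fold change of each tested member (x axis, mutant minus wild-type) of the 26 gene lists (y axis, number tested in brackets). Red points have an adjusted p under 0.05, grey points do not, diamonds are list medians and bars run from the lower to the upper quartile; the REST target list has a median of -0.88, and the erythroid list, with a median of -1.74 and no red point, is set by 1 wild-type library.

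In the lists of supporting, Schwann, mesenchyme, melanocyte, dark, endothelial, macrophage, otoconia and roof, and erythroid cells, 1 gene passed, Atp2b2 (edgeR adjusted p = 0.000775), which is also a hair cell gene. None of the supporting cell and prosensory genes passed over all genes or over the list (35 tested, median 0.05, camera adjusted p = 0.28), with Jag1 at 928 ± 55.3 and 898 ± 136 CPM and Notch2 at 786 ± 210.5 and 749 ± 61.1 CPM. The same held for Schwann cell, mesenchyme, melanocyte, dark cell, endothelial and macrophage lists, with medians of 0.02, 0.02, -0.17, -0.14, 0.04 and -0.01 and camera adjusted p of 0.528, 0.0872, 0.621, 0.655, 0.416 and 0.717. Without mutant replicate 1 the lists of mesenchyme and otic capsule genes (median 0.08, adjusted p = 0.00769) and of macrophage and leukocyte genes (0.11, adjusted p = 0.0319) passed at the preset correlation. With all libraries and an estimated correlation their adjusted p were 0.549 and 0.935. Of the otoconia and roof list 1 of 16 fell, Atp2b2 (median 0.0042, mean -0.10, camera adjusted p = 0.26). Examples are Sox9 at 1878 ± 227 and 1789.5 ± 202 CPM, Coch at 1685 ± 171 and 1673 ± 189 CPM, Ptn at 1588 ± 212 and 1572 ± 95.2 CPM and Slc12a2 at 36.7 ± 4.09 and 31.3 ± 1.82 CPM. The list of erythroid genes had a median of -1.74, with none past the threshold (camera adjusted p = 0.0828). Wild-type replicate 4 held Hbb-bs at 2142 CPM against 153 to 185 CPM in the other wild-type libraries, and without it the median was 0.26 (adjusted p = 0.00347). Without wild-type replicate 1, 2 or 3 the list passed as lower (adjusted p = 0.00136, 0.0028 and 0.00573). These calls used the preset correlation, and with all libraries the adjusted p = 0.739 with an estimated correlation.

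Lists for proliferation, p53 and apoptosis, heat shock, interferon, mitochondrial, ribosomal protein and sex-linked genes did not pass either, with medians of 0.07, 0.04, 0.09, 0.28, -0.0025, 0.0091 and -0.28 and camera adjusted p of 0.105, 0.341, 0.27, 0.0631, 0.847, 0.327 and 0.28. Some passed when 1 library was left out. For proliferation genes the median was 0.10 without wild-type replicate 4 (adjusted p = 0.00523) and 0.11 without mutant replicate 2 (0.0243). For interferon response genes it was 0.40 without mutant replicate 1 (adjusted p = 0.00408) and 0.25 without mutant replicate 3 (0.0112). For ribosomal protein genes it was 0.09 without mutant replicate 2 (adjusted p = 0.000265), and 0.06 and 0.05 without wild-type replicates 1 and 2 (0.034 and 7.91e-05). For sex-linked marker genes it was -0.48 without mutant replicate 1 (adjusted p = 0.0319). These calls used the preset correlation, and with all libraries and an estimated correlation their adjusted p were 0.739, 0.655, 0.933 and 0.67. The sex-linked list joins female and male markers, so opposite shifts can cancel in its median and its camera test. Tested singly, its 5 genes had exact two-sided permutation p from 0.114 to 0.914. Top2a was at 246 ± 19.7 and 262 ± 12.3 CPM. Immediate early genes had a median of 0.44 (16 tested, 0 past the threshold over all genes, 7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000169, but adjusted p = 0.235 with an estimated correlation). Endoplasmic reticulum stress genes had a median of 0.12 (0 past over all genes, 2 higher adjusted over the list alone, camera adjusted p = 0.0221, but adjusted p = 0.549 with an estimated correlation, and 0.136 without wild-type replicate 3). Of the skeletal muscle genes 1 rose, Myog (13 tested, median 0.03, camera adjusted p = 0.0311, but adjusted p = 0.549 with an estimated correlation). The muscle call was also lost in 5 of the 8 fits that leave out a library, with adjusted p from 0.0558 to 0.0841.

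The 25 higher genes were 17 protein-coding genes, 7 pseudogenes and 1 transcript still to be classified. Tmem163, a zinc transporter gene, rose from 0.655 ± 0.198 to 95.4 ± 6.67 CPM (SD, n = 4 each, log2 change 7.16 ± 0.15, SE, edgeR adjusted p = 1.4e-09). Fam219b rose from 65.8 ± 6.82 to 248 ± 47.4 CPM, the kinase gene Hipk1 from 39.8 ± 18.0 to 163 ± 32.4 CPM and the muscle transcription factor gene Myog from 7.57 ± 2.09 to 23.1 ± 3.98 CPM (adjusted p = 3.22e-05, 0.00311 and 0.00311). Smaller increases, by 0.57 to 1.24 on the log2 scale, were found for Vav3, Lrig2, Ing5, Arhgef11, Ecel1, Tsn, Shisa4 and Lmna. Leaving out single libraries ended the calls of Arhgef11 and Ecel1 in 6 fits each, of Tsn in 5 and of Shisa4 in 4. The adjusted p rose up to 0.102 for Arhgef11, 0.0768 for Ecel1, 0.0886 for Tsn and 0.0543 for Shisa4. The call of Lmna was lost without wild-type replicate 3 (adjusted p = 0.05). The ribosomal protein pseudogene Rps3a2 was at 18.0 ± 3.31 and 2.92 ± 2.71 CPM, while its parent Rps3a1 fell to 492 ± 59.9 from 743 ± 29.8 CPM. Both are uncertain because they share sequence, and the call of Rps3a2 was lost in 6 fits that leave out a library (adjusted p up to 0.0609).

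Of the 25 higher genes 16 lie on chromosomes 1 and 3 (9 and 7), which hold 11.9% of the genes tested (exact hypergeometric p = 1.13e-09, for chromosomes chosen after the positions were seen). Tmem163 is at 127486546 to 127679548 and Myog at 134289989 to 134292548 on chromosome 1, and Hipk1 at 103739815 to 103791563 on chromosome 3 (GRCm38). Of the lower genes 33 of 173 (19.1%) lie on these chromosomes, also more than their share (exact hypergeometric p = 0.00418). None of 50 tested genes within 5 Mb of Rest on chromosome 5 passed the threshold with edgeR. Of these 50, 9 had an unadjusted p under 0.05, against 2273 of all 16990 genes tested. As a group the genes near Rest were slightly lower, with a median log2 change of -0.15. The camera p was 0.0182, and the median difference in mean log2 CPM was -0.11 (exact permutation p = 0.0286 over 70 assignments, the smallest possible).

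**Figure D3:**
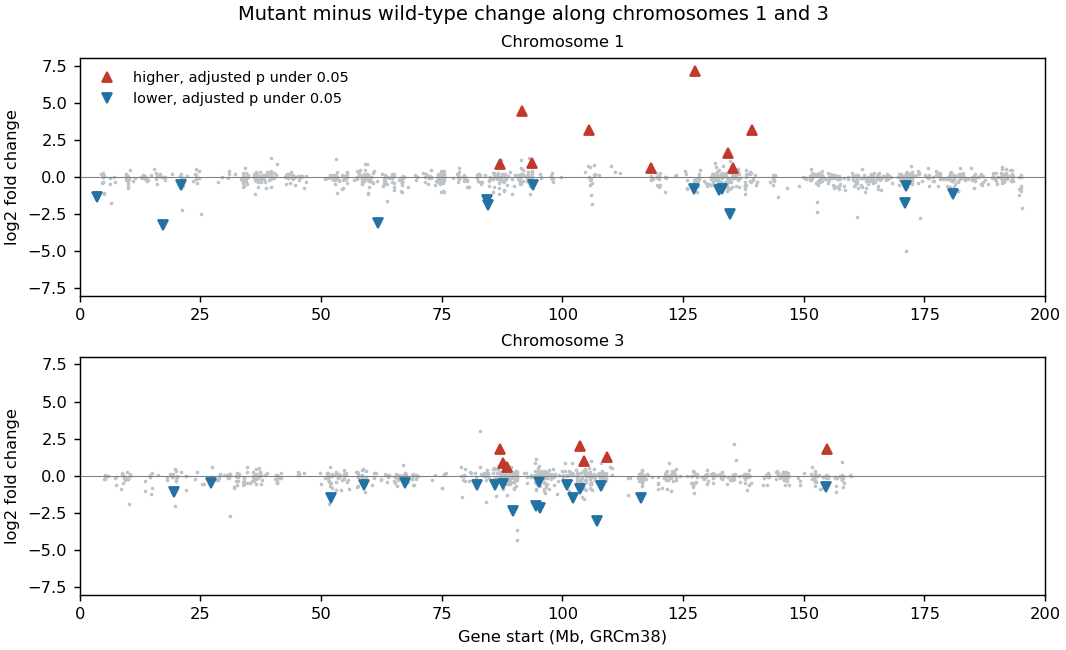
log2 fold change (y axis, mutant minus wild-type) of each tested gene against its start (x axis, Mb, GRCm38) on chromosomes 1 and 3; red upward triangles are higher and blue downward triangles lower at an adjusted p under 0.05, grey points are the other genes. The 9 higher genes of chromosome 1 start between 87.1 and 139 Mb.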

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

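The comparisons of lists, the position tests, the exact test near Rest, the liver gene counts and the genotype check were chosen only after the result was seen, while the fits that leave out a library and the regroupings of the libraries were planned.

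In 18 of 226 groups of 4 libraries (7.96%, where chance gives about 1 in 20), 1 library lay far from the others, its gap to the nearest divided by the range of the group being above the 5% critical value of Dixon's test. In the mutant group this was Rest (0.831) and mt-Rnr2 (0.835) in replicate 1, Rgs5 (0.862) in replicate 3, and Gdap1l1 (0.844) and Kcna10 (0.86) in replicate 4. In the wild-type group it was Jag1 (0.848), Ednrb (0.89) and the Schwann cell list (0.839) in replicate 1, and Hipk1 (0.926), Rps3a2 (0.941) and the immediate early list (0.85) in replicate 2. Wild-type replicate 3 stood apart for the REST target list (0.966), and replicate 4 for Kit (0.878), Rrm2 (0.845), Hbb-bs (0.984), Hbb-bt (0.978), the erythroid list (0.948) and the sex-linked list (0.841).

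Among the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many genes past the threshold: 198 in all, 173 lower and 25 higher, where the highest count of the other splits was 0. The other splits mix the genotypes, which widens the spread within their groups, so their lack of calls is a weak comparison. In the same way, only the real split reached the size of the median change of the REST target list (0.88, highest other 0.772). This also held for the hair bundle list (0.32, highest other 0.246) and the hair cell synapse list (0.51, highest other 0.342). A share of 1 split of 35 is the smallest possible and was not adjusted for the number of results read this way. It therefore argues against chance for these results but cannot exclude it. The hair bundle list had an adjusted p = 0.157 with an estimated correlation, so its call does not hold in that test. For the synaptic vesicle list 2 of 35 splits were as large (real value 0.32, highest other 0.338), so this count does not argue against chance there.

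REST target genes were lower in the mutant libraries (median log2 change -0.88). A lower number of hair cells is argued against as the whole cause. Hair cell transcription factor and early genes outside the REST list had a median of -0.0060 and quartiles of -0.38 and 0.24. The 95% bootstrap interval of their difference from the REST list was 0.40 to 1.56. Members moved both ways, so this median is only a rough measure of hair cell number. Hair bundle genes fell (median -0.32), though less than the REST list (interval of the difference 0.13 to 1.26), so fewer hair cells may be part of the cause. All bootstrap intervals here resampled genes and not libraries, so they do not measure the spread between pools. Less RNA of ganglion neurons is argued against too, since without wild-type replicate 3 the ganglion genes outside the REST list had a median of -0.089 against -0.57 for the REST list (lower quartile of the ganglion genes -0.26, interval of the difference 0.16 to 1.36), although the REST list fell less without that library. Liver and blood RNA in wild-type replicate 4 is excluded, since the median without that library was -0.95. An effect of the genotype on REST activity, and a change in hair cell maturity, may account for it and stay open as hypotheses.

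Genes higher in the mutant libraries lay together on chromosomes 1 and 3. The densest 60 Mb window held 9 of 25, against at most 8 in 10000 random placements (permutation p = 0.0001, the smallest they can give), and windows of 20 and 40 Mb, tried because the width was chosen by eye, gave p = 0.0037 and 0.0021. For the lower genes, whose densest windows also lay on chromosome 3, the permutation p was 0.169, 0.0735 and 0.118 at widths of 20, 40 and 60 Mb, but 19.1% of them lay on chromosomes 1 and 3 against 11.9% of genes tested (exact hypergeometric p = 0.00418). Sequence linked to the edited Rest allele is argued against for the genes of chromosomes 1 and 3 by position alone, since Rest lies on chromosome 5. The count of 0 called genes within 5 Mb of Rest does not bear on them. Linked sequence stays open for Gm5869, a higher pseudogene at 86997159 on chromosome 5 outside that window. It also stays open for the genes near Rest, which were slightly lower as a group (median difference in mean log2 CPM -0.11, exact permutation p = 0.0286). The strain labels do not separate the genotypes, and only that of wild-type replicate 4 differs from the others. Segments of another mouse strain carried in the line may be the cause, and Asb1 (named after its values were seen), at 4.397 CPM in mutant replicate 2 and 126 to 196 CPM in the other mutant libraries, varied within the group; wild-type replicate 2 was the highest wild-type library for 6 of 7 higher genes of chromosome 3, 5 of 9 of chromosome 1 and 6 of the 9 others, so also beyond these chromosomes, and as no sequence was compared here an effect of the genotype stays open.

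Wild-type replicate 4 held transcripts of liver and blood. Haemoglobin genes took 0.639% of its reads on genes against 0.047% to 0.0787% in the other libraries, and 20 liver genes took 0.315% against at most 0.00148%. Of the 20 liver genes 12 had been seen in these libraries before the list was written, and all 8 of the others were over 5 times higher than in any other library, by 12.7 to 2750 times, with Afp at 1172 CPM and Alb at 463 CPM; Ttr, Trf and Rbp4 are also measurable in the other libraries. RNA of liver and blood cells carried over in dissection or handling may be the source, and no biological explanation was tested. A wrong genotype label is argued against: for 96.4% of the 112 genes lower in the fit without this library, it lay on the wild-type side.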

How the results depend on the processing

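The alternatives that use the authors' libraries and genes, that leave out wild-type replicates 3 and 4 together, or that leave out chromosomes 1, 3 and 9 were chosen after seeing the data. All 198 genes past the threshold kept their sign in every alternative that tested them, 189 being tested under the stricter filter. The main counts, 25 higher and 173 lower, became 153 and 411 with DESeq2, whose calls included all 198. They became 10 and 68 at an adjusted p of 0.01, and 65 and 265 at 0.1, as a changed threshold must. Leaving out 1 library gave 12 to 28 higher and 105 to 140 lower genes, with fewer samples, and the authors' libraries and genes gave 112 lower. Without wild-type replicates 3 and 4 there were 71 lower, and without chromosomes 1, 3 and 9 there were 8 higher. With the replicate number as a block the counts were 16 and 80. Same-numbered libraries correlated at -0.15 to 0.07 in their deviations from the group means, and no library correlated best with its own number. These values gave no sign that the numbers pair the samples. They cannot exclude a pairing that affects few genes, and the labels do not say. The other size factors, filters, limma-voom fits, the sex-mix covariate and leaving out haemoglobin and mitochondrial genes kept both counts within 1.5 times. The list of canonical REST target genes (median -1.11 to -0.57) and the hair cell synapse list (-0.58 to -0.37) kept their direction and passed in every alternative. The hair bundle list (median -0.32, adjusted p = 0.157) and the synaptic vesicle list (-0.32, adjusted p = 0.157) did not pass with an estimated correlation (0.14 and 0.20). A higher correlation widens the variance of a list's mean, but this is not the whole reason. For the hair cell synapse list, with an estimated correlation of 0.0087, the unadjusted camera p also went from 7.94e-14 to 0.000272. The hair bundle and synaptic vesicle lists both passed with fry (adjusted p = 0.0146 and 0.0175). The ganglion, immediate early, endoplasmic reticulum stress and skeletal muscle lists did not pass with fry (adjusted p = 0.279, 0.0595, 0.146 and 0.338). The ratio of Rest was 1.06 without TMM factors (exact permutation p = 0.229). The list of erythroid genes did not pass in the main test (median -1.74). It passed as lower with DESeq2, with no filter, at 0.1 and without wild-type replicate 1, 2 (-2.065, adjusted p = 0.0028) or 3. It turned to a median of 0.26 and passed without wild-type replicate 4 (adjusted p = 0.00347) and with the authors' libraries and genes (0.26, adjusted p = 0.00345), and to 0.33 without wild-type replicates 3 and 4 (adjusted p = 0.0061), since that library holds the erythroid transcripts. Of 39 named genes past the threshold 28 passed at 0.01, 33 with the block and 27 without wild-type replicates 3 and 4. Srrm3 (adjusted p = 0.0515) passed with DESeq2, upper-quartile factors and both limma-voom fits. Where neither the main test nor the alternative passed, the sign changed in 22 of 431 list values and 63 of 895 gene values. The planned tests of genes near genomic RE1 sites, at each distance and with the backwards control, were not run because no genome sequence was used here. At this depth and number of libraries most 1.5-fold changes go uncalled. For the differences with DESeq2, the block and the left-out libraries the cause was not tested.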

Other observations

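The comparison of cilium genes below was chosen after the result was seen, and the search of transcripts for RE1 sites was set out before its result was seen.

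The cilium axoneme is the microtubule core of motile cilia and of the hair cell's kinocilium, and several of its genes were seen to be lower in the mutant libraries. In whole numbered families (Cfap, Dnah, Dnai, Dnaaf, Drc, Tekt and Rsph), 7 of 58 tested genes fell, none rose, and 52 had a negative change (median log2 change -0.38). No p is given for the set, because its families were picked after members had been seen to fall. Tekt2, a tektin of the axoneme, was at 49.9 ± 1.67 CPM in mutant and 74.5 ± 8.49 CPM in wild-type libraries (SD, n = 4 each), Drc1 at 31.3 ± 3.42 and 47.8 ± 5.50 CPM, Cfap161 at 5.87 ± 0.985 and 12.2 ± 1.10 CPM and Tekt4 at 3.10 ± 0.438 and 7.30 ± 1.32 CPM (edgeR adjusted p = 0.00884, 0.022, 0.0061 and 0.0108). These genes were named after their values were seen. A wider set of 89 genes, which includes single genes added because they had been seen to fall, had a median of -0.51 and overstates the change. Whether fewer hair cells account for this was not decided. The median of the hair cell transcription factor genes was -0.0060, but their quartiles were -0.38 and 0.24. The hair bundle genes fell by a similar amount (median -0.32, 95% bootstrap interval of the difference, resampling genes, -0.40 to 0.098). A change in the number or the maturity of hair cells may each be the cause.

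Protein-coding genes with a match to the 17-base RE1 consensus in an annotated transcript were searched as targets defined from sequence. The search covered 21901 genes of GENCODE M21, transcripts only, and found 154 genes with a match against 23 with the consensus written backwards. Of 84 tested genes 4 fell and none rose (Scn3b, Chrnb2, Rundc3a and Lhfpl5), with camera p = 0.0178 and p = 0.0185 with an estimated correlation, and the 20 tested genes of the backwards consensus gave p = 0.707. The median of the 84 genes was only -0.03. Outside the fixed REST target list, 1 of 77 fell and p was 0.607 with an estimated correlation, so the shift rests on genes already on that list and transcript matches add no separate evidence.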
